A study of Mus musculus with 15 samples.

How the data were processed

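The data were 15 RNA-seq libraries, 3 from each of 4 lens stages and 3 from whole embryos, as described in the report. The deposited values were FPKM per assembled transcript, made by the authors with Trimmomatic, TopHat2 2.0.9, Cufflinks and Cuffnorm on genome build mm10, per the submitters' processing notes. The notes do not give the order of these steps, the normalization setting or the read depth, so no precision that depends on depth can be given. The table held 48306 transcripts of 14650 gene symbols. Every transcript reached 1 FPKM in at least 2 libraries, so low transcripts had been removed before deposit. The FPKM sums of the libraries ran from 707562 to 1629915 and their median transcript values from 2.81 to 3.2.

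Gene values were computed as the sum of FPKM over the transcripts of a symbol, leaving out 172 transcripts of class x, which overlap an exon on the other strand. This left 14615 symbols. Genes with at least 1 FPKM in at least 3 of the 15 libraries were kept, which removed 80. A further 3 genes (Cryaa, Cryba1 and Nufip2) were left out of the tests, since they were listed at 0 in 1 or more libraries beside a replicate of at least 50 FPKM. Their values are given per library. The remaining 14532 genes were tested. Coordinates are from GENCODE vM21 on the same build. Of the 30879 reference transcripts in the table, 99.2% were found there, and 96.4% of those had the same symbol.

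Tests used limma 3.58.1 in R 4.3.3 on log2(FPKM + 1), with 1 mean per group, all 15 libraries in 1 fit and eBayes with a trended prior. This left 10 residual degrees of freedom. Each lens stage was compared with whole body, each stage with the stage before it, and E16.5 with E10.5, giving 8 contrasts. A moderated F test covered the 4 lens stages. A gene was called at a Benjamini-Hochberg adjusted p under 0.05, and counts are also given with a 2-fold minimum. No replicate block was used, since the labels do not say that replicate numbers mark a shared litter or day. As a check, matching replicate numbers correlated between groups with r from -0.0946 to 0.2373 over 30 pairs of groups' libraries, with 4 of them over 0.1. These 4 all lay among the later lens stages. They were replicate 1 of E12.5 with E14.5 (0.2373), of E12.5 with E16.5 (0.1611) and of E14.5 with E16.5 (0.1062), and replicate 2 of E14.5 with E16.5 (0.1967). A shared replicate factor in these stages is thus not excluded, and a replicate block was run as an alternative.

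For gene lists, 25 lists were fixed before the data were examined, from general knowledge of the lens and its surroundings. They were tested with limma's camera at a preset correlation of 0.01, with Benjamini-Hochberg adjustment over 200 list tests, and again with an estimated correlation and with fry. Genes enriched at 1 or more stages were grouped by k-means with 6 clusters and 50 starts, without a test. Overlap between stages was set beside 100 simulations of unchanged groups that shared the same controls. The named genes followed a rule fixed before the data were examined. For each contrast it took the 5 genes with the highest and the 5 with the lowest fold change among called genes with a mean of at least 10 FPKM in the higher group and no overlap between replicates. It added up to 2 members from each end of each list and a fixed set of lens genes. Some genes that the rule names are not reported here.

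The fits were tested on simulated data with 200 changed genes among 14532. The changed genes were drawn only from genes above a minimum mean FPKM, and the noise was normal with the spread of the fit. Recovery of genes with low values was therefore not tested. Of 1.5-fold changes 54% (E16.5 against E14.5) to 84% (E14.5 against whole body) were recovered, of 2-fold changes 90% to 94%, and 4 to 17 unchanged genes were called. Alternatives covered a pseudocount of 0.1, no filter, 3 rescalings of the values, a replicate block, fits of only the compared groups, eBayes without the trend, a 1.5-fold minimum and leaving out each library in turn. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15, using pandas 2.3.3.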

Results

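RNA-seq was used to follow gene expression in the lens of C57BL/6NTac mouse embryos at 4 stages from E10.5 to E16.5 (E, embryonic day), spaced 2 days apart. Each stage had 3 libraries, and 3 libraries of whole embryos (whole body), labelled as covering E10.5 to E12.5, served as the reference, giving 15 libraries in 5 groups. The labels call the libraries of a group biological replicates. Each lens library came from a pool of 50 lenses at E10.5, 29 at E12.5, 18 at E14.5 and 17 at E16.5. The labels do not say how embryos of different days were combined in the whole-body libraries. Values are FPKM (length- and library-scaled fragment values), summed over the transcripts of a gene, and 14532 genes were tested. The sequencing depth behind the values is unknown. Values are given as mean ± SD of 3 libraries, and log2 fold changes, computed on log2(FPKM + 1), as estimate ± SE. These fold changes understate the change of genes with low values. Unless a method is named, calls are from limma with Benjamini-Hochberg adjusted p. For gene lists, counts adjusted over the list alone are given where they differed from the counts over all genes. With an estimated correlation all 113 camera list calls were lost, so no list was called in any contrast. Even the crystallins at E14.5 against whole body, with a median log2 fold change of 13.709, had adjusted p = 0.23 there. With fry, 3 of the camera calls were lost.

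Libraries of 1 group resembled each other more than most libraries of other groups. Pearson's r of log2 values, across genes, ran from 0.980 to 0.994 within groups and from 0.694 to 0.987 between groups. Crystallins, the structural proteins of the lens, made up 0.054% ± 0.011 of the summed FPKM at E10.5, 10.48% ± 2.89 at E12.5, 26.9% ± 2.78 at E14.5 and 32.0% ± 4.76 at E16.5, against 0.0011% ± 0.0001 in whole body (SD, n = 3). The shares at E14.5 and E16.5 count Cryaa and Cryba1 at 0 in the libraries where they were listed at 0. Cryaa (alpha-crystallin; chromosome 17, 31677807 to 31681733 in mm10) stood at 25806, 41766 and 49433 FPKM in the E12.5 libraries, at 111417, 0 and 0 at E14.5 and at 0, 0 and 140912 at E16.5. Cryba1 (beta-crystallin; chromosome 11, 77718615 to 77725283) stood at 83497, 81759 and 78722 FPKM at E14.5 and at 0, 0 and 101407 at E16.5. Nufip2, a broadly expressed gene on the other strand of the Cryba1 locus, was also at 0 in those 2 E16.5 libraries and at 82.9 FPKM in the third. These 3 genes were therefore left out of the tests.

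Comparing lens with whole embryo at E10.5 asks which transcripts were enriched at the stage of the lens pit and early vesicle. Genes of the early lens already stood far above whole body. Foxe3, a forkhead factor of the lens epithelium (chromosome 4, 114925147 to 114926013), was at 302 ± 28.4 FPKM against 0.4 ± 0.11 in whole body, a log2 fold change of 7.76 ± 0.13 (adjusted p = 7.49e-15). Pax6, the paired-box factor of eye development (chromosome 2, 105668900 to 105697364), was at 449.8 ± 5.69 against 29.9 ± 1.02 FPKM (3.87 ± 0.06). The retinaldehyde dehydrogenases Aldh1a1 (7.91 ± 0.18) and Aldh1a3 (6.34 ± 0.46) and the crystallin Crybb3 (6.35 ± 0.20) were also higher. Of the 18 lens transcription factors, 10 were higher, 4 lower and 4 not called (camera adjusted p = 0.0001, or adjusted p = 0.23 with an estimated correlation). Pitx3 was higher by 5.46 ± 0.14 and Maf by 3.57 ± 0.14, while Sox11 (-1.58 ± 0.19) and Meis2 (-1.28 ± 0.11) were lower. All 14 crystallins tested were higher (camera adjusted p = 9.35e-11, fry adjusted p = 1.46e-07, or camera adjusted p = 0.235 with an estimated correlation). At this stage 12 of them stayed under 40 FPKM. Of the 13 fibre membrane and cytoskeleton genes, 7 were higher, 2 lower (Tmod1 and Hspb1) and 4 not called (camera adjusted p = 0.00493, or adjusted p = 0.42 with an estimated correlation).

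Other groups differed at E10.5 too. Of 82 cytosolic ribosomal protein genes, 77 were higher than in whole body, 2 lower and 3 not called (78 and 2 over the list alone, camera adjusted p = 2.45e-25, or adjusted p = 0.256 with an estimated correlation). Rpl29 was at 366 ± 26.6 against 80 ± 9.12 FPKM. Of 17 glycolysis genes 12 were higher, 2 lower and 3 not called (camera adjusted p = 0.000145, or adjusted p = 0.303 with an estimated correlation). Among them were Eno1 (2.00 ± 0.12) and the glucose transporter Slc2a1 (1.61 ± 0.09). All 10 cardiac and skeletal muscle markers and all 9 neuron markers were lower, led by Actc1 (-6.48 ± 0.24) and Dcx (-6.45 ± 0.20). The muscle test gave camera adjusted p = 2.16e-09, or adjusted p = 0.23 with an estimated correlation. The neuron test gave camera adjusted p = 2.27e-07, or adjusted p = 0.23 with an estimated correlation. The positional gene Hoxd4, expressed along the trunk, was at 0.06 ± 0.056 against 87.9 ± 15.2 FPKM (-6.38 ± 0.13). Markers of other cells around the eye stood beside these groups. Of the macrophage markers 10 of 11 were higher and 1 not called (camera adjusted p = 0.000119, or adjusted p = 0.299 with an estimated correlation). All 6 pigment cell markers were higher (camera adjusted p = 0.00233, or adjusted p = 0.311 with an estimated correlation). In the endothelium list 7 of 10 were higher, 1 lower and 2 not called (8 and 1 over the list alone, camera adjusted p = 0.021, or adjusted p = 0.537 with an estimated correlation). Periocular mesenchyme markers were lower in 6 of 11, with 0 higher and 5 not called (0 and 7 over the list alone, camera adjusted p = 0.116). The surface epithelium list had 3 higher, 5 lower and 1 not called of 9 (camera adjusted p = 0.629), and the erythroid list 1 higher and 9 lower of 10 (camera adjusted p = 0.0519). The retina factor Six6 (4.15 ± 0.37) was higher too. The list of neural retina markers had 5 higher, 3 lower and 2 not called of 10 (camera adjusted p = 0.479).

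At E10.5, 3568 genes were higher and 4527 lower than in whole body, of which 942 and 1979 passed the 2-fold minimum. The 3 E10.5 libraries differed in liver-type transcripts: the mean of 7 liver markers was 4.64, 1.16 and 5.32 on the log2(FPKM + 1) scale in replicates 1, 2 and 3, against 3.91 to 4.16 in whole body. They differed in markers of surrounding tissue as well. In replicates 1, 2 and 3 the periocular mesenchyme means were 4.342, 4.266 and 6.291, the pigment cell means 2.57, 4.137 and 4.047 and the erythroid means 7, 5.775 and 5.745. Without replicates 1 and 3 of E10.5, a check chosen after seeing the data, 950 genes were higher and 1969 lower at the 2-fold minimum. With quantile normalization 1528 genes were higher, and 49.0% of the 2-fold calls were higher instead of 32.2%, against 29.9% with crystallins left out and totals made equal. Quantile normalization moved the median of all genes by 0.103 on the log2 scale.

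**Figure D1:**
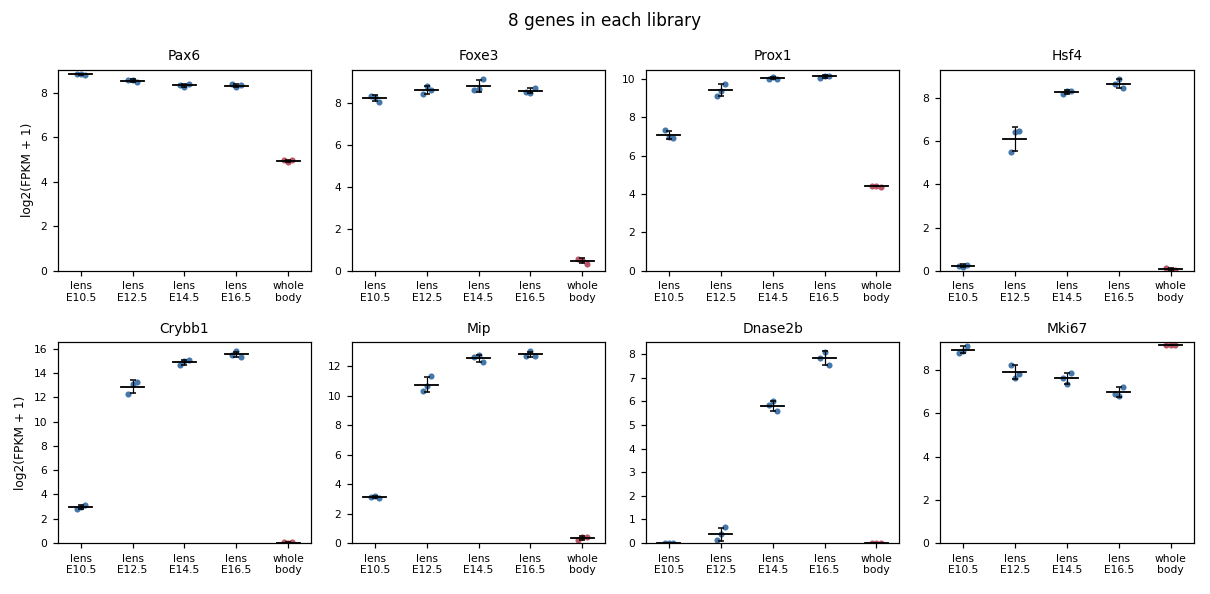
Each panel plots log2(FPKM + 1) of 1 gene (vertical axis) in the 15 libraries, grouped by lens stage and whole body (horizontal axis), with points for libraries, a line for the group mean and bars for the SD of 3 libraries. Foxe3 lay near 8 to 9 in every lens group and near 0 in whole body, whereas Dnase2b was above 5 at E14.5 and E16.5 and near 0 elsewhere.

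At E12.5, when the posterior vesicle cells elongate into primary fibres, crystallins and fibre genes stood far above whole body. Crybb1 (chromosome 5, 112255815 to 112269585) was at 7834 ± 2596 FPKM against 0.027 ± 0.023 (12.84 ± 0.20) and Crybb3 at 11218 ± 3131 (12.91 ± 0.20). All 14 crystallins were higher (camera adjusted p = 1.82e-13, or adjusted p = 0.23 with an estimated correlation). Cryga was at 6142 ± 2864 FPKM and listed at 0 in all whole-body libraries. Gamma-crystallins such as Cryga, Cryge and Crygf are closely similar copies, so their separate levels are uncertain. Of 13 fibre genes 9 were higher, 1 lower and 3 not called (camera adjusted p = 2.95e-06, or adjusted p = 0.242 with an estimated correlation). All 4 lens RNA-binding protein genes were higher (camera adjusted p = 0.000375, or adjusted p = 0.235 with an estimated correlation). Of 18 lens transcription factors 14 were higher and 4 lower (camera adjusted p = 6.09e-05, or adjusted p = 0.23 with an estimated correlation). Among them was Sox1 (3.18 ± 0.16), a regulator of gamma-crystallins.

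Cell cycle genes were lower than in whole body at E12.5: 26 of 28, with 0 higher and 2 not called (camera adjusted p = 1.4e-06, or adjusted p = 0.427 with an estimated correlation). Of 42 cataract-linked genes outside the crystallins, 30 were higher, 5 lower and 7 not called (camera adjusted p = 1.71e-09, or adjusted p = 0.23 with an estimated correlation). Of 44 genes of respiratory chain complexes I and III, 36 were higher and 8 not called (camera adjusted p = 1.56e-08, or adjusted p = 0.311 with an estimated correlation). The collagen IV gene Col4a6 (4.29 ± 0.17) and Nid1 (3.10 ± 0.12) of the lens capsule were higher. The basement membrane list had 12 higher, 1 lower and 4 not called of 17 (camera adjusted p = 0.000345, or adjusted p = 0.263 with an estimated correlation). Macrophage markers were higher in 10 of 11 and not called in 1 (11 and 0 over the list alone, camera adjusted p = 0.000532, or adjusted p = 0.333 with an estimated correlation). The surface and corneal epithelium markers were lower in 9 of 9 (camera adjusted p = 0.00112, or adjusted p = 0.23 with an estimated correlation). All 6 pigment cell markers were higher (camera adjusted p = 0.0164, or adjusted p = 0.42 with an estimated correlation). Periocular mesenchyme markers were lower in 5 of 11, with 0 higher and 6 not called (0 and 4 over the list alone, camera adjusted p = 0.159). The endothelium list had 1 higher and 9 not called of 10 (0 and 0 over the list alone, camera adjusted p = 0.562). The erythroid list had 3 higher, 5 lower and 2 not called of 10 (camera adjusted p = 0.955), and the neural retina list 4, 5 and 1 of 10 (camera adjusted p = 0.947). In total 4690 genes were higher and 5391 lower, 1602 and 2568 of them by at least 2-fold. Leaving crystallins out and making totals equal, 2 changes made together, moved the median of all genes by -0.178 and the share of higher genes among the 2-fold calls from 38.4% to 29.3%. Quantile normalization moved that share the other way, to 48.8%. The 3 E12.5 libraries differed in both lens and surrounding-tissue transcripts. Their crystallin means were 9.26, 9.97 and 10.32 and their periocular mesenchyme means 5.84, 4.78 and 4.21 on the log2(FPKM + 1) scale in replicates 1, 2 and 3.

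At E14.5 and E16.5 lens groups stood above whole body, and cell cycle genes and several lists of tissue markers below it. Whole body covers E10.5 to E12.5 only, so these 2 comparisons mix tissue with embryonic age. The comparisons at E10.5 and E12.5 may do so as well, since it is unknown how the days were combined in whole body. Hbb-bs, a globin of adult red cells, went from a log2 fold change of -3.62 against whole body at E10.5 to 1.76 at E16.5. Bfsp1, a beaded filament protein of fibres, was at 3056 ± 395 FPKM at E14.5 and 9463 ± 1772 at E16.5 against 1.03 ± 0.044 in whole body (10.55 ± 0.20 and 12.17 ± 0.20). Mip, the fibre water channel (chromosome 10, 128225838 to 128231812), was at 6109 ± 972 and 7353 ± 871 FPKM (12.22 ± 0.19 and 12.49 ± 0.19). Hsf4, a heat shock factor of fibres (chromosome 8, 105269801 to 105275845), was at 402 ± 57.6 FPKM at E16.5 against 0.063 ± 0.04 (8.56 ± 0.19). Fibre genes were higher in 11 of 13 at E14.5, with 1 lower and 1 not called, and in 13 of 13 at E16.5 (camera adjusted p = 2.94e-07 and 4.19e-09, or adjusted p = 0.23 and 0.23 with an estimated correlation). Crystallins were higher in 14 of 14 at both stages (camera adjusted p = 8.92e-12 and 1.85e-11, or adjusted p = 0.23 and 0.23 with an estimated correlation). The lens epithelium genes were higher in 6 of 8 at E16.5, lower in 1 (Meis1) and not called in 1 (camera adjusted p = 0.00275, or adjusted p = 0.23 with an estimated correlation).

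All 28 cell cycle genes were lower than in whole body at E14.5 and at E16.5 (camera adjusted p = 2.12e-07 and 4.19e-09, or adjusted p = 0.409 and 0.338 with an estimated correlation). Mki67, a marker of dividing cells (chromosome 7, 135689784 to 135716361), was at 127 ± 20.5 FPKM at E16.5 against 575 ± 7.05 (-2.18 ± 0.16). Respiratory chain genes were higher in 42 of 44 at both stages with 2 not called (camera adjusted p = 1.35e-11 and 2.29e-11, or adjusted p = 0.26 and 0.263 with an estimated correlation). Ndufa1 reached 507 ± 39.8 FPKM at E16.5 against 25.8 ± 2.13 (4.25 ± 0.11). With crystallins left out and totals made equal, 33 of the 44 were higher at E16.5 and 2 lower. Ribosomal protein genes were higher in 79 of 82 at E14.5 with 3 lower, and in 78 at E16.5 with 3 lower and 1 not called (camera adjusted p = 4.11e-17 and 5.23e-15, or adjusted p = 0.311 and 0.337 with an estimated correlation). Autophagy and mitophagy genes were higher in 11 of 15 at E16.5, lower in 3 and not called in 1 (camera adjusted p = 0.00641, or adjusted p = 0.272 with an estimated correlation). These were led by the receptor Optn (4.46 ± 0.14) and Gabarapl1 (2.66 ± 0.12). All 11 periocular mesenchyme markers were lower at E14.5 and at E16.5 (camera adjusted p = 0.00121 and 0.00145, or adjusted p = 0.338 and 0.345 with an estimated correlation). Surface epithelium markers were lower in 8 of 9 at both stages, with 1 not called at E14.5 and 1 higher at E16.5 (camera adjusted p = 0.00293 and 0.00623, or adjusted p = 0.23 and 0.23 with an estimated correlation). The macrophage markers were lower in 10 of 11 and higher in 1 at E14.5 (camera adjusted p = 0.0996), and lower in 8 with 3 not called at E16.5 (camera adjusted p = 0.103). Pigment cell markers were higher in 3 of 6 at E14.5 with 3 not called (camera adjusted p = 0.206), and in 4 with 2 not called at E16.5 (3 and 0 over the list alone, camera adjusted p = 0.102). Endothelium markers were lower in 8 of 10 at E14.5 and in 7 at E16.5, with 2 and 3 not called (camera adjusted p = 0.0643 and 0.158, or adjusted p = 0.629 and 0.68 with an estimated correlation). Erythroid markers were lower in 7 of 10 at both stages, with 2 higher and 1 not called (camera adjusted p = 0.124 and 0.0684, or adjusted p = 0.695 and 0.649 with an estimated correlation). Neural retina markers were lower in 6 of 10 at E14.5 with 4 not called (0 and 5 over the list alone, camera adjusted p = 0.0511), and lower in 5, higher in 2 and not called in 3 at E16.5 (camera adjusted p = 0.235).

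The embryonic globins were among the lowest against whole body at E16.5: Hbb-y was at 1.86 ± 0.74 against 3930.4 ± 482 FPKM (-10.45 ± 0.38) and Hba-x at 1.11 ± 0.24 against 2136 ± 208 FPKM (-9.99 ± 0.43). At E14.5, 5187 genes were higher and 6188 lower, with 2390 and 3684 past the 2-fold minimum. At E16.5, 5348 were higher and 6300 lower, with 2688 and 3804 past it. With crystallins left out and each library rescaled to 1 common total, 1551 and 1654 genes were higher by 2-fold at E14.5 and E16.5. Under that scaling the median of all genes moved by -0.405 and -0.476 on the log2 scale. The share of higher genes among the 2-fold calls moved from 39.3% to 24.1% and from 41.4% to 23.7%. Quantile normalization moved these shares the other way, to 49.1% and 48.4%, and the E14.5 median by 0.111.

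**Figure D2:**
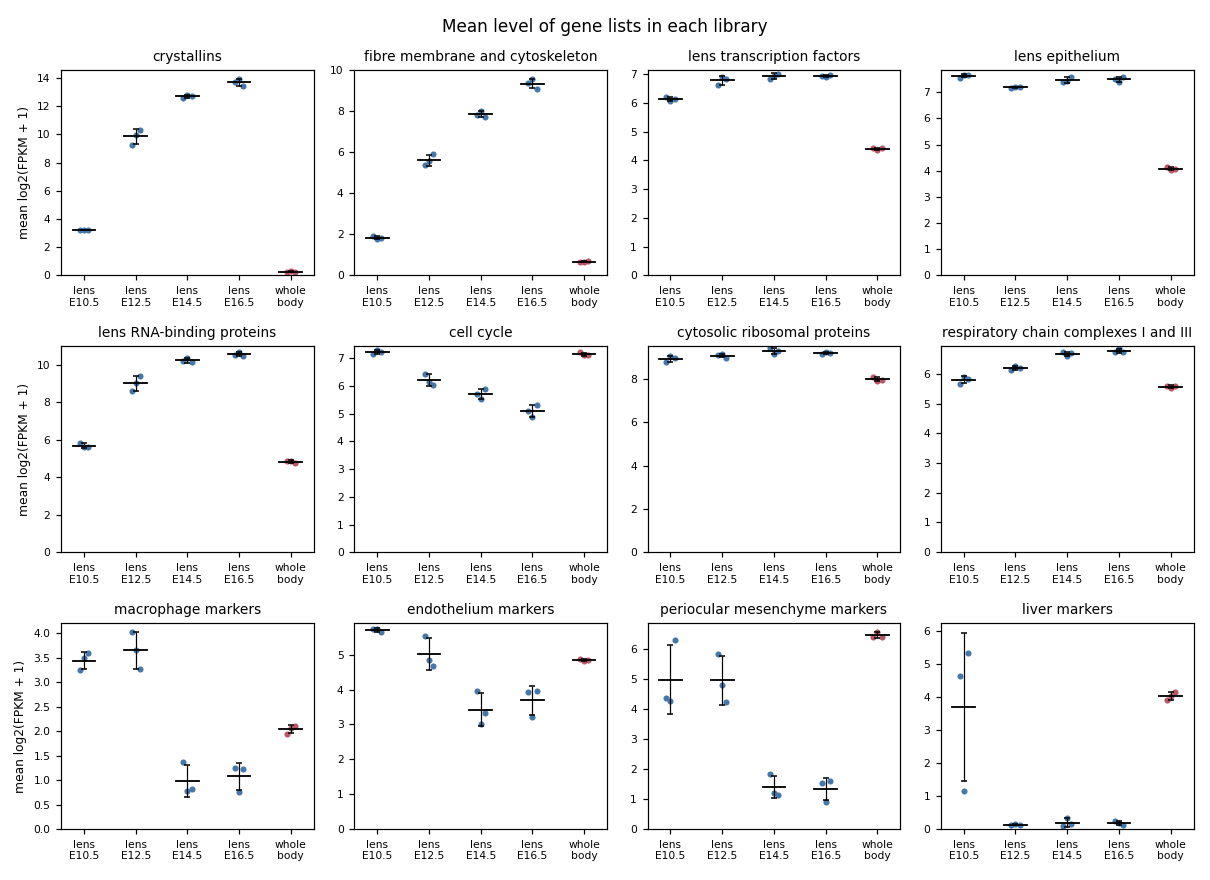
Each panel plots the mean log2(FPKM + 1) of 1 gene list (vertical axis) in the 15 libraries, grouped by lens stage and whole body (horizontal axis), with points for libraries, a line for the group mean and bars for the SD of 3 libraries. The crystallin means of the lens libraries ran from 3.20 at E10.5 to 13.90 at E16.5, and the liver markers of the E10.5 libraries were spread from 1.16 to 5.32.

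Comparing successive lens stages asks which genes change as fibres form. From E10.5 to E12.5 the crystallins rose by a median log2 fold change of 6.973. Crybb1 rose from 6.88 ± 0.95 to 7834 ± 2596 FPKM (9.90 ± 0.20, adjusted p = 1.1e-13) and Cryba4 from 3.71 ± 0.35 to 2509.7 ± 990.3 (8.98 ± 0.20). All 14 crystallins rose (camera adjusted p = 1e-14, or adjusted p = 0.23 with an estimated correlation). Lim2, a fibre membrane protein (8.24 ± 0.16), and Mip (7.62 ± 0.19) rose as well. Of 13 fibre genes 9 rose, 1 fell (Hspb1) and 3 were not called (camera adjusted p = 2.58e-07, or adjusted p = 0.23 with an estimated correlation). Among the lens regulators, Prox1 (chromosome 1, 190118035 to 190170714) rose from 135 ± 21.3 to 692 ± 155 FPKM (2.34 ± 0.13), and Maf (chromosome 8, 115682942 to 115707794) rose by 1.94 ± 0.14. Sox1 rose by 3.31 ± 0.16 and Hsf4 from 0.17 ± 0.05 to 71 ± 24 FPKM (5.87 ± 0.19). Sox2 changed by -2.47 ± 0.16. Of the 18 transcription factors 11 rose, 6 fell and 1 was not called (11 and 7 over the list alone, camera adjusted p = 0.199). All 4 RNA-binding protein genes rose (camera adjusted p = 0.000104, or adjusted p = 0.23 with an estimated correlation), among them Tdrd7 by 3.88 ± 0.18 and Caprin2 by 4.04 ± 0.18.

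Proliferation genes moved the other way between E10.5 and E12.5. Of 28 cell cycle genes 27 fell and 1 was not called (0 and 28 over the list alone, camera adjusted p = 3.22e-12, or adjusted p = 0.284 with an estimated correlation). Mki67 changed by -1.03 ± 0.16. Of 8 cell cycle exit genes 7 rose and 1 was not called (camera adjusted p = 7.11e-05, or adjusted p = 0.23 with an estimated correlation). The cyclin-dependent kinase inhibitor Cdkn1c rose from 139 ± 9.11 to 851 ± 133 FPKM (2.60 ± 0.12). Glycolysis genes fell in 13 of 17, rose in 2 and were not called in 2 (camera adjusted p = 0.000344, or adjusted p = 0.314 with an estimated correlation). The transporter Slc2a3 went from 64.2 ± 10.3 to 6.73 ± 2.55 FPKM (-3.11 ± 0.21). Surface epithelium markers fell in 6 of 9 and were not called in 3 (camera adjusted p = 0.00275, or adjusted p = 0.23 with an estimated correlation). Krt8 changed by -4.25 ± 0.34, Epcam by -3.78 ± 0.38 and Trp63 by -3.81 ± 0.15. In the endothelium list 1 of 10 rose, 6 fell and 3 were not called (1 and 8 over the list alone, camera adjusted p = 0.0566), and in the erythroid list 5 rose, 1 fell and 4 were not called (camera adjusted p = 0.0759). The neural retina list had 1 risen, 5 fallen and 4 not called of 10 (2 and 5 over the list alone, camera adjusted p = 0.23). The periocular mesenchyme list had 1 risen, 3 fallen and 7 not called of 11 (camera adjusted p = 0.681). The macrophage list had 2 risen and 9 not called (0 and 0 over the list alone, camera adjusted p = 0.797), and no pigment cell marker was called (camera adjusted p = 0.611). The FGF receptor Fgfr3 rose from 5.39 ± 2.01 to 120.1 ± 33.1 FPKM (4.27 ± 0.21). In the FGF signalling list 3 of 14 rose, 4 fell and 7 were not called (camera adjusted p = 0.955). Liver markers fell in 6 of 7 and were not called in 1 (camera adjusted p = 0.00851, or adjusted p = 0.442 with an estimated correlation). Their mean was 0.13 to 0.14 in the E12.5 libraries, against the 1.16 to 5.32 of the E10.5 libraries given above. The Notch signalling list had 3 risen, 3 fallen and 5 not called of 11 (camera adjusted p = 0.967). In total 4280 genes rose and 3779 fell, 1240 and 1067 of them by at least 2-fold. Leaving crystallins out and making totals equal moved the median by -0.108 and the share of rises among the 2-fold calls from 53.7% to 42.5%, and quantile normalization moved that share to 49.8%.

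From E12.5 to E14.5 most fibre genes rose, many of them from levels already above whole body. Dnase2b, the nuclease that degrades fibre cell DNA (chromosome 3, 146580985 to 146615596), rose from 0.32 ± 0.25 to 55.6 ± 8.25 FPKM (5.43 ± 0.18, adjusted p = 5.2e-11), and was listed at 0 in all E10.5 and whole-body libraries. Bfsp1 rose from 132 ± 46.1 to 3056 ± 395 FPKM (4.57 ± 0.20), Bfsp2 by 3.16 ± 0.20, Lctl by 4.01 ± 0.17 and the gamma-crystallins Crygf (5.92 ± 0.27) and Crygb (4.96 ± 0.25) as well. Fibre genes rose in 11 of 13 and were not called in 2 (11 and 1 over the list alone, camera adjusted p = 4.09e-09, or adjusted p = 0.23 with an estimated correlation). All 14 crystallins rose (camera adjusted p = 7.51e-14, or adjusted p = 0.23 with an estimated correlation). The mitophagy receptor Optn went from 10.6 ± 1.5 to 92.5 ± 9.46 FPKM (3.02 ± 0.14). Of 15 autophagy and mitophagy genes 9 rose, 1 fell and 5 were not called (camera adjusted p = 0.000532, or adjusted p = 0.23 with an estimated correlation). Respiratory chain genes rose in 37 of 44 with 7 not called (39 and 0 over the list alone, camera adjusted p = 1.94e-13, or adjusted p = 0.243 with an estimated correlation). Of 17 glycolysis genes 12 rose, 2 fell and 3 were not called (13 and 2 over the list alone, camera adjusted p = 0.000438, or adjusted p = 0.322 with an estimated correlation). With crystallins left out and totals made equal these counts were 24 risen and 1 fallen for the respiratory chain and 9 and 3 for glycolysis.

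Several lists of markers of surrounding tissue fell over the same interval. All 11 macrophage markers fell (camera adjusted p = 2.3e-09, or adjusted p = 0.23 with an estimated correlation). Csf1r went from 29.9 ± 10.8 to 1.76 ± 1.34 FPKM (-3.54 ± 0.31). All 11 periocular mesenchyme markers fell (camera adjusted p = 1.3e-06, or adjusted p = 0.232 with an estimated correlation). Col3a1 went from 243 ± 168 to 6.32 ± 4 FPKM (-4.99 ± 0.73). Endothelium markers fell in 9 of 10 with Tek not called (camera adjusted p = 0.000119, or adjusted p = 0.311 with an estimated correlation). Erythroid markers fell in 8 of 10 with 2 not called (0 and 9 over the list alone, camera adjusted p = 3.77e-05, or adjusted p = 0.317 with an estimated correlation). Of 10 neural retina markers 7 fell, 1 rose and 2 were not called (camera adjusted p = 0.000619, or adjusted p = 0.256 with an estimated correlation). The pigment cell list had 3 fallen, 1 risen and 2 not called of 6 (2 and 4 over the list alone, camera adjusted p = 0.318). The surface epithelium list had 4 fallen, 1 risen and 4 not called of 9 (camera adjusted p = 0.0684). Cell cycle genes fell in 22 of 28 and were not called in 6 (0 and 24 over the list alone, camera adjusted p = 7.87e-07, or adjusted p = 0.42 with an estimated correlation). In total 3088 genes rose and 3258 fell, with 594 and 1131 past the 2-fold minimum. With crystallins left out and totals made equal the share of rises among the 2-fold calls was 21.9%, and with quantile normalization 45.8%, instead of 34.4%. The first of these moved the median by -0.208.

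From E14.5 to E16.5 fewer genes changed: 868 rose and 586 fell, 233 and 42 by at least 2-fold. The small heat shock gene Hspb1 rose from 0.25 ± 0.12 to 40.8 ± 14.9 FPKM (4.996 ± 0.28, adjusted p = 5.21e-08), the lipoxygenase Alox15 from 0.14 ± 0.14 to 17.6 ± 7.19 (3.97 ± 0.20) and the sarcomere actinin gene Actn2 from 5.53 ± 2.12 to 98.7 ± 31.8 (3.93 ± 0.37). Crygs rose from 278 ± 10.7 to 1113 ± 279.9 FPKM (1.96 ± 0.15) and Cryab by 1.28 ± 0.14, among 8 of 14 crystallins that rose. The crystallin list had 8 risen, 0 fallen and 6 not called (13 and 0 over the list alone, camera adjusted p = 1.22e-10, or adjusted p = 0.235 with an estimated correlation). Fibre genes rose in 9 of 13 and were not called in 4 (11 and 0 over the list alone, camera adjusted p = 7.14e-13, or adjusted p = 0.23 with an estimated correlation). Cell cycle genes fell in 27 of 28 and were not called in E2f1 (1 and 27 over the list alone, camera adjusted p = 1.22e-20, or adjusted p = 0.23 with an estimated correlation). Rrm2 changed by -0.88 ± 0.13. The Wnt antagonist Sfrp2 went from 138 ± 20.8 to 18.9 ± 7.23 FPKM (-2.85 ± 0.19). Among the markers of surrounding tissue, the macrophage list had 1 fallen and 10 not called (camera adjusted p = 0.877). Erythroid markers fell in 2 of 10 and were not called in 8 (camera adjusted p = 0.000627, or adjusted p = 0.41 with an estimated correlation). Neural retina markers rose in 2 of 10 and were not called in 8 (3 and 0 over the list alone, camera adjusted p = 0.0928). No periocular mesenchyme, endothelium, pigment cell or surface epithelium marker was called. The 2-fold decreases numbered 90 with a pseudocount of 0.1 and 21 in a fit of only these 2 groups.

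Over the whole interval from E10.5 to E16.5, 5404 genes rose and 5338 fell, 2493 and 2650 by at least 2-fold. Leaving crystallins out and making totals equal gave 1577 that rose by 2-fold, and the median moved by -0.384 and the share of rises among the 2-fold calls from 48.5% to 28.5%. That share was 47.5% with quantile normalization. All 13 fibre genes, 14 crystallins and 4 RNA-binding protein genes rose, and all 28 cell cycle genes fell (camera adjusted p = 3.86e-12, or adjusted p = 0.284 with an estimated correlation). For fibre genes the test gave camera adjusted p = 1.72e-09, or adjusted p = 0.23 with an estimated correlation. For crystallins it gave camera adjusted p = 1.89e-11, or adjusted p = 0.23 with an estimated correlation, and for RNA-binding genes camera adjusted p = 0.00125, or adjusted p = 0.258 with an estimated correlation. All 11 macrophage markers fell (camera adjusted p = 0.000224, or adjusted p = 0.311 with an estimated correlation), as did all 11 periocular mesenchyme markers (camera adjusted p = 0.0014, or adjusted p = 0.345 with an estimated correlation). Endothelium markers fell in 9 of 10 and rose in 1 (camera adjusted p = 0.00641, or adjusted p = 0.456 with an estimated correlation). Surface epithelium markers fell in 6 of 9, rose in 1 and were not called in 2 (camera adjusted p = 0.0248, or adjusted p = 0.256 with an estimated correlation). Neural retina markers fell in 6 of 10, rose in 1 and were not called in 3 (camera adjusted p = 0.0524). Erythroid markers fell in 6 of 10, rose in 2 and were not called in 2 (camera adjusted p = 0.0928). Pigment cell markers fell in 3 of 6, rose in 1 and were not called in 2 (camera adjusted p = 0.519). Caprin2 rose from 23.4 ± 3.23 to 2768 ± 316 FPKM (6.83 ± 0.18) and Tdrd7 (chromosome 4, 45965334 to 46034761) to 2642 ± 304 (6.41 ± 0.18). Pax6 fell by 0.50 with an SE of 0.06 and stood at 318 ± 13.8 FPKM at E16.5, against 29.9 ± 1.02 in whole body. Aldh1a3 went from 536 ± 78.1 to 3.72 ± 2.95 FPKM (-7.11 ± 0.46). Cataract-linked genes rose in 34 of 42, fell in 6 and were not called in 2 (35 and 6 over the list alone, camera adjusted p = 1.27e-07, or adjusted p = 0.23 with an estimated correlation). Ribosomal protein genes rose in 45 of 82, fell in 2 and were not called in 35 (44 and 2 over the list alone, camera adjusted p = 0.00493, or adjusted p = 0.712 with an estimated correlation). This direction turned with 7 risen and 35 fallen when crystallins were left out and totals made equal, and 3 risen and 59 fallen with quantile normalization. A moderated F test over the 4 lens stages called 11237 of the 14532 genes.

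Lens-enriched genes were grouped by the stages at which they stood at least 2-fold above whole body, whose embryos were younger than the E14.5 and E16.5 lenses. In all, 3341 genes were enriched at 1 or more stages and 401 at all 4 stages. Unchanged groups simulated with shared controls gave 0 genes at all 4 stages, and independent lists of these sizes would share 3.16. Neither sizes the overlap to be expected here. The simulation left every gene unchanged and gave a mean of 0.08 genes at 1 or more stages. Stages of the same tissue are not independent lists. Part of the overlap may come from the shared whole-body libraries, which could not be checked, since 3 controls cannot be parted into 2 equal sets. The most frequent sets were E12.5 with E14.5 and E16.5 (979 genes), E14.5 with E16.5 (847), all 4 stages (401), E16.5 alone (383) and E10.5 alone (374). Of the 3341 genes, 1977 were higher at E16.5 than at E10.5 by at least 2-fold, 404 were lower and 960 neither. Quantile normalization gave 653 genes at all 4 stages, and leaving crystallins out with totals made equal gave 1220 that were higher.

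Grouping the 3341 genes into 6 clusters by their 4 enrichment values (k-means, no test) placed 11 crystallins and 6 fibre genes in a cluster of 20 genes. Its mean log2 enrichment went from 3.24 at E10.5 to 10.13, 12.76 and 13.41 at the later stages. A cluster of 94 genes (2.06, 4.91, 6.13 and 6.48) held 6 lens transcription factors and 3 RNA-binding genes. A cluster of 830 genes (0.49, 1.42, 2.02 and 2.22) held 36 ribosomal protein genes. In the cluster of 403 genes with enrichment at E10.5 (1.58, 0.39, -0.81 and -0.74) lay 9 macrophage, 6 endothelium, 4 neural retina and 3 surface epithelium markers and no crystallin. A cluster of 1661 genes (0.184, 0.69, 1.089 and 1.283) held 32 ribosomal protein and 21 respiratory chain genes, and the last cluster had 333 genes. The assignments depended on the settings, with an adjusted Rand index against this grouping of 0.505 for 4 clusters, 0.669 for 8 and 0.472 for a pseudocount of 0.1.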

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

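The tests in this part were chosen after the results they bear on had been seen, except the test of visceral endoderm markers, which was set before its values were looked at.

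In 128 genes the lens libraries were at least 2-fold above whole body at E10.5 and at least 2-fold below it at E16.5. The change between these stages was itself called. Among them were Crym (-6.83 ± 0.31 from E10.5 to E16.5, log2 ± SE, n = 3 per group), Krt8 (-6.44 ± 0.34) and Epcam (-6.19 ± 0.38), and 5 endothelium, 3 macrophage and 3 surface epithelium markers. Krt8 and Epcam are among those surface epithelium markers. How many more of the 128 belong to cells around the lens was not counted. The liver marker Apoa1 was also among them. Its log2 fold change against whole body at E10.5 was 2.24, and -0.8632 without E10.5 replicates 1 and 3. In 115 genes the turn was the opposite, from below whole body at E10.5 to above it at E16.5. Examples were the acetylcholine receptor subunit Chrng (8.47 ± 0.16), Pla2g7 (8.43 ± 0.24) and Pgam2 (8.08 ± 0.23). Chrng, Pla2g7 and Pgam2 were singled out here after their values were seen, as the ends of the ranking.

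Cryaa reached 140912 FPKM and Cryba1 101407 FPKM in the highest lens library, outside the comparisons made here, while both were at or near 0 in whole body. Cryaa was listed at 0 in 4 and Cryba1 in 2 of the E14.5 and E16.5 libraries. A library without fibre RNA, or with a wrong label, would lower the other crystallins too, but the 14 others differed by a median of 0.19 on the log2 scale (-0.05 to 1.07) between libraries with Cryaa at 0 and the rest of their stage. A candidate explanation is a failed estimate for the whole locus in the deposited values: Nufip2, on the same assembled locus as Cryba1, was at 0 in 2 of the 2 libraries with Cryba1 at 0 and at 55.7 FPKM or more elsewhere. No such neighbour was tested for Cryaa.

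Liver-type transcripts were high in E10.5 replicates 1 and 3, with Afp at 339.6, 6.91 and 625.2 FPKM and Ttr at 47.7, 2.41 and 83.0 in replicates 1, 2 and 3. RNA of the whole embryo would also raise muscle and neuron markers, whose median difference from replicate 2 was 0.18 on the log2 scale, with 7 of 19 higher in both libraries. Embryonic liver as the only source is argued against by Alb, at 0.35 and 0.12 FPKM against 33.74 to 44.63 in whole body: at the ratios of those embryos of mixed days, a liver share sized by this 1 gene would bring a median of 0.129% of the excess of 17 liver and visceral endoderm markers (0.433% in replicate 1 and 0.059% in replicate 3, with Dab2 highest at 287% in replicate 1). A candidate source is yolk sac tissue: 11 of 11 visceral endoderm markers were higher in both, with a median difference of 3.09. Among them Dab2 hardly differed, at 37.96 FPKM in replicate 1 against 37.74 in replicate 2. The marker test was set for yolk sac or liver tissue alike, so its result alone cannot tell these sources apart. No biological explanation was tested, since replicates of 1 stage differ in nothing the labels name.

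Markers of cells around the lens were lower at E14.5 than at E12.5. Dilution by crystallin transcripts is argued against by their change relative to all genes, -2.39 on the log2 scale with crystallins left out and totals made equal, and -2.44 as deposited. Whether all surrounding cell types were lost alike stays open. The medians of 6 lists ranged over 2 on the log2 scale, from -3.07 for periocular mesenchyme to -1.06 for pigment cells. The Kruskal-Wallis statistic gave permutation p = 0.0086 (58 genes), but this test takes single genes as independent. The pigment genes Mitf, Trpm1, Oca2 and Tyr also lay in clusters that rose in the lens, while Dct and Pmel lay in the cluster that fell. Members of other lists lay in rising clusters too: Hba-a2, Hbb-bt and Hbb-bs (erythroid), Atoh7 (neural retina) and Lyz2 (macrophage). Less adhering tissue in older dissections may contribute. The periocular mesenchyme, endothelium, erythroid and macrophage lists deviated together within stages, with a mean correlation of 0.61 over 12 libraries (permutation p = 0.00015). It was 0.93 without E10.5, and the neural retina and pigment cell lists were not included. Deviation within stages does not itself show less tissue at E14.5 than at E12.5. A change of these tissues with embryonic age remains open and was not tested. In the erythroid list, the embryonic globins Hbb-y and Hba-x were far below whole body at E16.5. The adult globin Hbb-bs was above it (log2 fold change 1.76). The fall of this list therefore need not measure loss of tissue alone.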

How the results depend on the processing

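Alternatives chosen after seeing the data were genes with a failed 0 kept, antisense transcripts added, reference transcripts only and E10.5 replicates 1 and 3 both left out, where the lone E10.5 library was assumed to vary like the other groups. The alternative for counts was not run, since the values are FPKM. Where a result moved, the cause was not tested, except that a 1.5-fold minimum admits more genes by construction. Read depth is unknown, so what it limits cannot be stated.

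Of 909 results for named genes, 909 were kept without a filter, 897 with median-ratio rescaling and 901 with a replicate block. In fits of only the compared groups 850 were kept, and with quantile normalization 846. A called result was kept if its call and direction held. A result called in neither setting counted as kept whatever its sign. With crystallins left out and totals made equal, 2 changes made together here and below, 796 of the 852 results that remained were kept. Crystallin genes had no value there. With the replicate block, 7 genes passed the threshold that otherwise did not, 1 no longer did, and 9 of 200 list tests were newly called. With an estimated correlation 113 list calls were lost and none was kept. With fry, in contrast, 48 list tests were newly called and 3 calls were lost, and with a pseudocount of 0.1 camera newly called 7. Some lists given above as not called by camera were thus called by fry, such as surface epithelium at E10.5 against whole body (fry adjusted p = 0.000695).

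A 1.5-fold minimum gave these counts. Against whole body it gave 1861 higher and 3045 lower at E10.5, 2944 and 3901 at E12.5, and 3738 higher at E14.5. Between stages it gave 2435 and 2294 from E10.5 to E12.5, 1366 and 1983 to E14.5, 488 and 215 to E16.5, and 3891 higher from E10.5 to E16.5. Enriched genes numbered 5187 at 1 or more stages, 849 at all 4, 3125 rising and 826 falling. Quantile normalization gave 1528 higher at E10.5 and 653 enriched at all 4 stages. With crystallins left out, 1551 and 1654 were higher than whole body at E14.5 and E16.5, 1577 rose from E10.5 to E16.5, and 1220 enriched genes rose. The 42 decreases from E14.5 to E16.5 became 90 with a pseudocount of 0.1 and 21 in a fit of only these groups. Cluster assignments had an adjusted Rand index of 0.505 with 4 clusters, 0.669 with 8 and 0.472 with a pseudocount of 0.1.

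A change is listed as reversed where its sign turned and it was called in either setting, so some were no longer called after the turn. Reversed log2 changes with crystallins left out were, against whole body, Cdkn1b (-0.0116 at E12.5, -0.2029 at E14.5, -0.2532 at E16.5), Ndufs1 (-0.4377 at E14.5), Pdgfra (-0.4487), Ndufv1 (-0.4633) and Egfl7 (-0.416) at E16.5. From E12.5 to E14.5 they were Ndufv1 (-0.1789) and Cdkn1b (-0.1913), and from E10.5 to E16.5 Ndufs1 (-0.3509), Uqcrb (-0.3033) and Foxe3 (-0.1255). Under this scaling Cdkn1b at E12.5 and Foxe3 were not called. With quantile normalization they were, against whole body, Ndufs1 (-0.2731) and Aif1 (0.1024) at E14.5 and Pdgfra (-0.4106), Ndufv1 (-0.165) and Lyz2 (0.7324) at E16.5. Between stages they were Rpsa (-0.094 to E12.5, -0.697 from E10.5 to E16.5), Rpl41 (-0.1291) and Cdkn1c (-0.0235) to E14.5, and Ndufs1 (-0.1781) and Foxe3 (-0.2089) from E10.5 to E16.5. With quantile normalization Aif1, Rpsa to E12.5, Rpl41, Cdkn1c and Foxe3 were not called. With reference transcripts only they were Pdgfra (-0.8144 at E16.5 against whole body), Cdh1 (-0.1183) and Map2 (-0.1092) to E14.5, Elavl4 (-0.2132) to E16.5 and Map2 (-1.9036) from E10.5 to E16.5. Of these, Cdh1, Map2 to E14.5 and Elavl4 were not called with reference transcripts only. Without E10.5 replicates 1 and 3, Apoa1 (-0.8632) and Ttr (-1.6787) against whole body and Myl4 (0.037) to E12.5 reversed. Afp against whole body at E10.5 ranged from -1.8649 to 1.2885 when 1 library was left out; it reversed to the upper value without E10.5 replicate 2.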

Other observations

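The counts of other splits of the libraries in this part were chosen as tests after the results had been seen.

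Some further genes and lists were compared between E10.5 and E16.5 or with whole body. The Notch ligand Jag1 went from 147 ± 9.36 FPKM at E10.5 to 566 ± 30.4 at E16.5 (1.94 ± 0.10, log2 ± SE, n = 3 per group), against 43.8 ± 1.12 in whole body. Of 11 Notch signalling genes, 2 were higher and 9 lower than in whole body at E16.5 (camera adjusted p = 0.12). From E10.5 to E16.5, 4 of them rose, 4 fell and 3 were not called (camera adjusted p = 0.797). The splicing regulator Celf1 rose by 1.97 ± 0.13 and Rbm24 by 4.31 ± 0.15 over this interval. Of 44 respiratory chain genes 42 rose, 0 fell and 2 were not called over this interval (camera adjusted p = 2.4e-10, or adjusted p = 0.284 with an estimated correlation), or 29 rose and 4 fell with crystallins left out and totals made equal. Glycolysis genes rose in 7 of 17, fell in 5 and were not called in 5 (camera adjusted p = 0.819), with 4 risen and 10 fallen under that scaling and 3 and 13 with quantile normalization.

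Other splits of the libraries were counted for each comparison, with fits of only the libraries compared. With 3 libraries against 3 there are 10 splits, too few for a share under 0.05, and 1 of 10, the real one, gave as many genes in each contrast. Against whole body the real split gave 2913 genes at E10.5, 4162 at E12.5, 6070 at E14.5 and 6489 at E16.5, and the highest other split 0. From E10.5 to E12.5 it gave 2201 (highest other 0), from E12.5 to E14.5 1588 (highest other 1), from E14.5 to E16.5 179 (highest other 1) and from E10.5 to E16.5 5095 (highest other 0). For the F test over the 12 lens libraries, 1 of 100 splits, the real one, gave as many as its 10813 genes, and the highest other gave 10102. The real stages gave more genes than any other split tried, and a share of 0.01 is the lowest that 100 splits can give. The highest other split came close, but other splits can keep libraries of 1 stage together and so hold part of the real stage differences. Their counts give no level for unchanged stages. How close they came therefore does not measure how far apart the stages stood.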
